A study of Homo sapiens with 36 samples.

How the data were processed

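Total RNA from bone marrow plasma cells of 36 human multiple myeloma samples was hybridised to oligonucleotide arrays. Per the labels, mononuclear cells were separated on a density gradient, plasma cells were selected with magnetic beads against CD138, and purity was checked by flow cytometry, light chain staining and morphology. The labels put all samples in 1 group, labelled MRI-no-lytic-lesion, and gave no batch, date or second group.

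The deposited values are linear probe set intensity, 1 value for each probe set on each array. The software, version and detection calls behind these intensities are not given in the sources used here. Tested on the values, the mean after trimming 2% at each end was 1500.75 on average and differed by at most 1.000233-fold between arrays, so the deposited intensities had been scaled to a common trimmed mean. Array medians still ranged from 421.5 to 632.9 and the highest signal from 31503 to 144250.7. No array pair was identical (0 pairs), and log2 signals of 2 arrays correlated across probe sets at r from 0.844 to 0.932. 5 values were 0. All sample columns of the table were used.

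Values below 106.6, the 20th percentile of all values, were set to that floor and log2 was taken. Of the probe sets, 11506 were listed in the platform annotation and 1119 were not. 10961 had 1 gene symbol, 545 had several and were named for none, and 10949 had 1 symbol with a current human gene record. 67 control probe sets, Y-linked genes, XIST and TSIX were left out of gene tests. Probe sets had to exceed the median of their own array in at least 4 samples, and the probe set with the highest mean represented each gene, leaving 5873 of 8203 genes. Probe sets of the same list gene or named gene had a median r of 0.498 over 170 comparisons.

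The gene lists, 20 lists of 477 genes of which 324 were tested, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. That rule took DKK1, the measured Wnt antagonists and the cyclin D and translocation targets, and for each genome-wide relation the 10 largest slopes in each direction past the threshold or, where none passed, the 5 lowest p. It further took the 20 genes with the highest SD outside the immunoglobulins, the 4 members of each list with the highest SD, and in the single gene tests the genes that passed or the 3 with the lowest p. For lists whose relation with DKK1 passed, it took up to 4 members with the largest r. Genes named outside this rule (CTNNB1, SDC1, XBP1 and CXCR4 within lists, ZWINT and MCM5, FUT8, the immunoglobulins, and the bright or uneven genes of the closing section) were chosen after their values were seen, except those a test below named beforehand. 1 of the 20 genes with the highest SD is not reported here. A list score was the mean over members of standardised log2 signals, for lists of at least 3 members, which left the Wnt antagonists without a score.

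Genome-wide relations were fitted with limma 3.58.1 in R 4.3.3, log2 signal on log2 DKK1 or on the standardised proliferation score, two-sided, with Benjamini-Hochberg adjustment at 0.05. Other relations used Pearson's r and Spearman's rho with two-sided tests of 100000 permutations, adjusted within families of 19 lists, 41 genes, 171 pairs of lists and 100 relations with array measures, and r was repeated without the 2 samples farthest from the median of the x variable. A gene whose sorted values had a gap over 1 SD with at least 3 samples on each side got no pooled r. List coherence was tested one-sided against 10000 random lists matched on deciles of expression. camera and fry were run on the limma fit, and Fisher's exact test compared lists with the most variable genes. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 were used.

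The scripts were tested on simulated data. With 5872 genes, 200 of them following the real DKK1 values, the limma step recovered 97.6% of genes with a true r of 0.7 and 44.8% with a true r of 0.5, and 4.6% of its calls were false. The coherence test called 10 of 10 coordinated lists and 0 of 10 others, and the permutation test 20 of 20 true relations and 1 of 20 others.

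Alternatives were quantile normalization, no further scaling, floors at the 5th and 40th percentile, no filter and a filter of 18 samples on dim probe sets, the probe set with the highest SD, ranks, the GAPDH 3′ to 5′ ratio or cell type scores as covariates, array weights, the median absolute deviation scaled to the SD of a normal distribution, other thresholds, an estimated correlation, and leaving out samples. Array background (the mean log2 signal of 23 control probe sets for bacterial, mouse and yeast sequences), array maximum and array median as covariates were chosen after seeing the data. DKK1 itself was kept under the filter of 18 samples, which it does not pass. No genome was used, so no coordinates are given.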

Results

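RNA from CD138-selected bone marrow plasma cells of multiple myeloma, a cancer of antibody-secreting cells, was measured on 36 oligonucleotide arrays. All 36 samples carried the same label, MRI-no-lytic-lesion, and formed 1 group. No second group was available, so the comparisons below are relations between genes across the 36 samples, and none is a difference between patients with and without bone lesions. The keywords in the labels name DKK1, Wnt signalling, osteoblasts and osteolytic lesions, which made DKK1 and its relatives the first question. Signal is given on the log2 scale after a floor at 106.6, as mean ± SD over samples. The labels do not state that each array came from a different patient, so p-values measure the spread between these samples. The median signal of an array ranged from 421.5 to 632.9, and the number of arrays limits the precision.

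DKK1, a secreted antagonist of Wnt signalling, had signals that differed widely between samples of this single group. It averaged 8.42 ± 1.31 (SD, n = 36), with a median signal of 285 and a range from 19.2 to 3810. The 90th percentile of the samples was 1051, and the 10th (49.8) lay below the floor, so no fold between them is given. Only 10 of the 36 samples were brighter for DKK1 than the median of their own array, and 6 lay at the floor. The SD of DKK1 exceeded that of 94.7% of the genes tested, but the floor sets part of it, and with a floor at the 40th percentile of all values the SD was 0.918. FRZB, another secreted Wnt antagonist, had a larger SD, at 9.41 ± 2.77 (SD, n = 36), with 12 samples at the floor. DKK4 averaged 9.30 ± 0.67 (SD, n = 36). The other 10 of the 13 Wnt antagonists listed beforehand had no probe set among the genes tested.

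**Figure D1:**
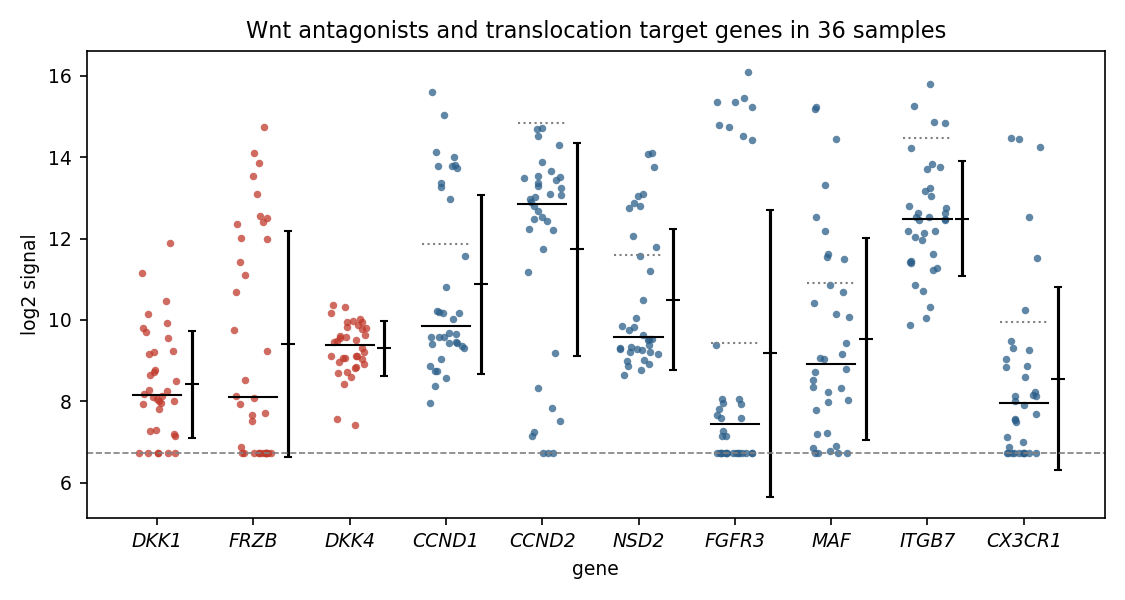
Log2 signal of 3 Wnt antagonists (red) and 7 cyclin D or translocation target genes (blue) in 36 samples, 1 point per sample; horizontal bars are medians, error bars to the right are mean ± SD, the dashed line is the floor, and dotted lines lie 2 above the median. The largest gap between neighbouring samples, with at least 3 samples on each side, is 0.377 SD for DKK1 and 1.43 SD for FGFR3.

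DKK1 was then set against every other gene. No gene followed it: limma called 0 of 5872 genes at an adjusted p under 0.05, 311 genes had an unadjusted p under 0.05, and the lowest adjusted p was 0.869. The genes with the lowest p on the positive side, none passing, were RNF216 (slope 0.41 ± 0.11 SE per log2 unit of DKK1, n = 36), the RNA helicase gene DDX49 (0.20 ± 0.05), DAGLA (0.48 ± 0.14), the ribosome biogenesis gene RRS1 (0.26 ± 0.08) and the glycolysis regulator PFKFB4 (0.31 ± 0.09). On the negative side they were the semaphorin receptor gene PLXNA3 (-0.32 ± 0.08), the leukocyte integrin gene ITGAL (-0.43 ± 0.12), PPP1R26 (-0.31 ± 0.09), GNB2 (-0.17 ± 0.05) and the homeobox gene EN2 (-0.25 ± 0.08), also with adjusted p = 0.869 by limma. The slope of GNB2 depended on the probe set and was 0.02 with the other choice. In simulated data of the same size, 97.6% of genes with a true r of 0.7 and 44.8% of those with a true r of 0.5 were recovered for this comparison. There 200 genes followed DKK1, other variation was independent between genes, and no floor was set. With fewer such genes the adjusted threshold is stricter, so these shares do not apply to a few genes following DKK1.

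None of the gene lists, all fixed before the data were examined, passed with DKK1: by permutation test 0 of 19 list scores passed and 1 had an unadjusted p under 0.05. The adhesion and migration list had the strongest relation with DKK1: its score ran opposite to DKK1 at r = -0.453 (95% interval -0.680 to -0.146, rho = -0.375 with p = 0.0259, n = 36). Its permutation p was 0.0059 and its adjusted p over 19 lists 0.1117 (0.491 on ranks), so it did not pass, and r without the 2 samples farthest from the median of DKK1 was -0.383. Members of this list with a wide spread were the tetraspanins CD9 (10.63 ± 2.28) and CD81 (10.62 ± 2.08) and the chemokine receptors CCR1 (8.65 ± 1.95) and CCR2 (12.28 ± 1.67, all SD, n = 36). Within the list 0 genes passed over all genes tested, and 1 of 22, ITGAL, passed when adjusted over the list alone (adjusted p = 0.0173 by limma). The list score passed at r = -0.499 (adjusted p = 0.0389) once the granulocyte, erythroid, monocyte, and T and NK cell scores were covariates. Without replicate 23 it passed as well, at r = -0.519 (adjusted p = 0.0279). The same score ran opposite to the 3′ to 5′ ratio of beta-actin, a sign of RNA quality (r = -0.501, rho = -0.504, adjusted p = 0.0151).

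The camera test with a preset correlation called 2 of 19 lists. Adhesion and migration was lower with higher DKK1 (adjusted p = 0.0109) and passed with an estimated correlation too (adjusted p = 0.0363 with an estimated correlation). The interferon response list was higher with higher DKK1 (adjusted p = 0.0109), a call lost otherwise (adjusted p = 0.947 with an estimated correlation). Its score had r = 0.219 with DKK1, and 0.0089 without the 2 samples farthest from the median of DKK1. The fry test, which asks whether a list moves one way on balance, gave an adjusted p of 0.121 for adhesion and migration and 0.963 for the interferon response. For every list other than adhesion and migration, 0 members passed when adjusted over the list alone. The remaining 17 lists had r with DKK1 between -0.222 (B cell) and 0.124 (Wnt ligands, receptors and effectors), with adjusted p = 0.995. The median and mean slope of the members differed in sign for 4 lists, among them T and NK cell (median 0.0012, mean -0.0442).

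**Figure D2:**
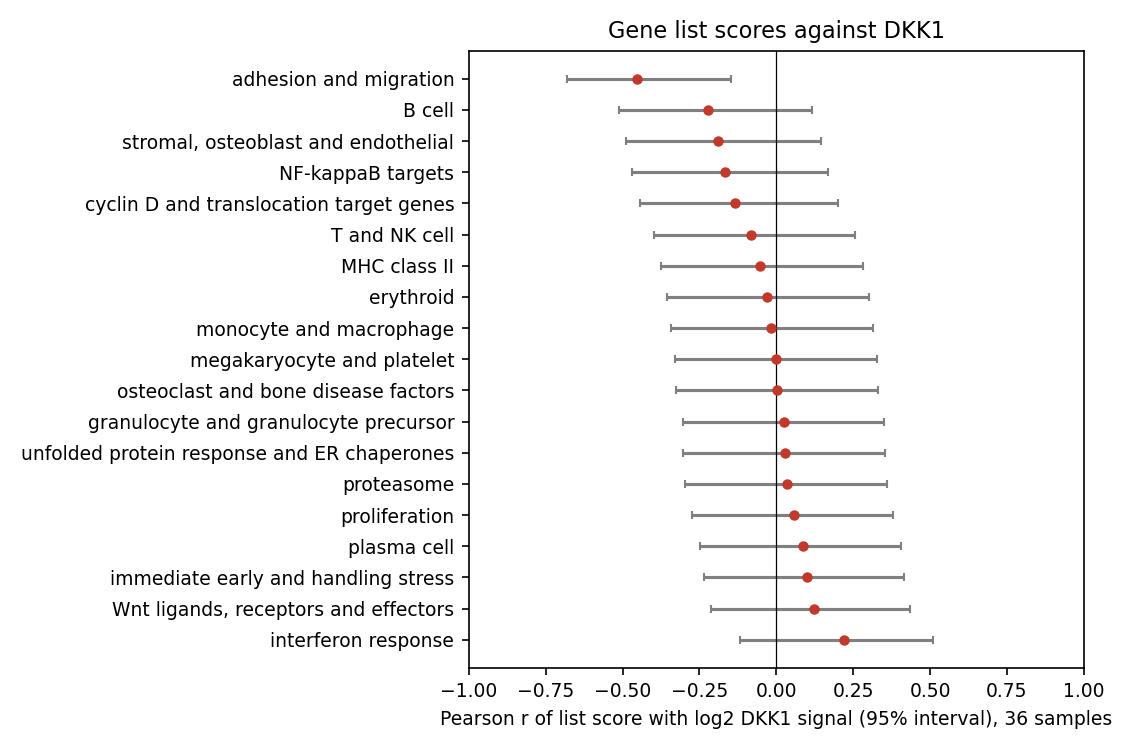
Pearson r between each of 19 list scores and log2 DKK1 signal over 36 samples, with 95% intervals. The interval for adhesion and migration (-0.680 to -0.146) leaves out 0, but its adjusted p of 0.1117 does not pass.

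Wnt pathway genes and factors known from myeloma bone disease were tested singly against DKK1, 41 genes in all, and 0 passed while 2 had an unadjusted p under 0.05. CSNK1A1, a kinase that primes beta-catenin for degradation, had r = 0.431 (rho = 0.454, permutation p = 0.0087 and 0.0058, adjusted p = 0.3587 and 0.236, n = 36), and 0.401 without the 2 samples farthest from the median of DKK1. AXIN1, the scaffold of the same destruction complex, had r = -0.335 (rho = -0.286, permutation p = 0.0457 and 0.0929, adjusted p = 0.915 and 0.762), and -0.261 without the same 2 samples. IL6, a plasma cell growth factor, had the third lowest p, but its samples fell into clusters with a gap of 1.14 SD, so no pooled r is given. FRZB had r = 0.224 with DKK1 (95% interval -0.113 to 0.515, rho = 0.266, permutation p = 0.1893 and 0.1184, adjusted p = 0.938 and 0.809), and 0.230 without the same 2 samples, so the 2 antagonists were not shown to move together or apart. For DKK4, whose r with DKK1 was -0.150 (rho = -0.0157, permutation p = 0.386 and 0.927, adjusted p = 0.938 and 0.994), the sign turned to 0.0832 without the 2 samples farthest from the median of DKK1, and to 0.0253 without replicate 32.

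Of the Wnt ligands, receptors and effectors, 21 of 35 were measured and 4 had an SD over 1. These were WNT5A (9.70 ± 1.88), the transcription factor gene LEF1 (9.03 ± 1.56), the receptor gene FZD7 (9.08 ± 1.37) and WNT10B (10.79 ± 1.26, all SD, n = 36). CTNNB1, which encodes beta-catenin, was bright and even, at 12.62 ± 0.35. Among the 18 measured osteoclast and bone disease factors, 7 had an SD over 1, led by SPP1 (osteopontin, 8.46 ± 2.94), the chemokine genes CCL3 (11.27 ± 1.94) and CCL4 (8.78 ± 1.63), and IL6 (7.80 ± 1.73). For SPP1, with 17 of 36 samples at the floor, and IL6 the spread came from part of the samples, with scaled median absolute deviations of 0.29 and 0.34. The bone disease factors as a list moved with the median signal of the array (r = 0.613, rho = 0.592, adjusted p = 0.0040), and the Wnt ligands, receptors and effectors did so at r = 0.458 (rho = 0.468, adjusted p = 0.0396).

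Many genes differed widely between samples of this group: 859 of 5873 genes had an SD over 1, against a median SD of 0.61. The count was 418 with the floor at the 40th percentile and 474 with the filter of 18 samples. Immunoglobulin genes, which follow the clone, made up 11 of them. The most variable of the others was FGFR3, a receptor tyrosine kinase gene activated by translocation in myeloma (9.19 ± 3.53, SD, n = 36). Others with a high SD were CST6, a cysteine protease inhibitor gene (9.55 ± 3.01), SPP1, the deubiquitinase gene UCHL1 (10.50 ± 2.80), FRZB, FAM30A (10.22 ± 2.69) and the metalloproteinase inhibitor gene TIMP1 (12.14 ± 2.63). CCND2, MAF, CX3CR1 and CCND1 are described with the translocation targets. Further genes of the first 20 were RNASE6 (9.24 ± 2.59), the interferon-induced IFI27 (8.64 ± 2.44), the memory B cell marker CD27 (11.85 ± 2.40), CD99 (10.61 ± 2.32), LAPTM5 (11.47 ± 2.30), the NADPH oxidase gene CYBB (11.50 ± 2.29), CD9 and the thromboxane synthase gene TBXAS1 (11.16 ± 2.21). A second probe set for CST6 had an SD of 0.62 and r = 0.229 with the one used, whereas for SPP1 that r was 0.980.

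Several cyclin D and translocation target genes were far above their median in some of the samples, and some pairs were high together. CCND1, the cyclin gene activated by the translocation of chromosomes 11 and 14, was over 2 log2 units above its median in 11 of 36 samples (10.87 ± 2.21). NSD2, a histone methyltransferase gene, was that high in 10 samples (10.50 ± 1.74) and FGFR3 in 9, with both genes high in 8, where 2.5 would be expected if they were independent. Both are targets of the translocation of chromosomes 4 and 14. CCND1 and NSD2 were both high in 1 sample, against 3.06 expected. MAF, a transcription factor gene, was high in 9 samples (9.53 ± 2.48), CX3CR1, the fractalkine receptor gene, in 6 (8.56 ± 2.25) and the integrin gene ITGB7 in 4 (12.49 ± 1.42). All 4 samples high in ITGB7 were high in CX3CR1 (0.667 expected), and MAF and CX3CR1 were both high in 3 (1.5 expected). MAF was also high in 3 samples each with CCND1 (2.75 expected), NSD2 (2.5) and FGFR3 (2.25), close to the numbers expected if independent. The samples in these overlaps had MAF between 11.50 and 13.31. Replicate 18 stood in each of them, over the mark for CCND1 (13.26), NSD2 (13.04), FGFR3 (15.25) and MAF (13.31). It was also the 1 sample high in both CCND1 and NSD2. The brightest MAF samples, replicates 24, 28 and 31 (15.19, 15.24 and 14.44), were over the mark for none of CCND1, NSD2 and FGFR3. CCND2 ran the other way, bright in most samples (11.73 ± 2.62) and over 2 below its median in 9. Each of those 9 samples was over the mark for CCND1. CCND3 (11.99 ± 0.85), IRF4 (14.20 ± 0.56), CDKN1A (13.08 ± 0.62) and CDKN2A (7.98 ± 0.80) were over 2 above their medians in 0 samples. No test was made between samples marked in this way. MAF and CCND1 had further probe sets, which followed the ones used at r of 0.919, and 0.902 and 0.969.

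Of 20 lists, 8 were enriched among the 294 genes (5% of those tested) with the highest SD, by a one-sided Fisher's exact test. Immediate early and handling stress genes had 13 of 28 members there (adjusted p = 3.63e-09), with CCL3, the G protein regulators RGS1 (10.06 ± 1.82) and RGS2 (11.50 ± 1.79) and the phosphatase gene DUSP2 (9.04 ± 1.67) varying most. Adhesion and migration had 10 of 22 (adjusted p = 3.22e-07), cyclin D and translocation targets 7 of 11 (1.36e-06), the interferon response 9 of 26 (1.28e-05), monocyte and macrophage 6 of 14 (0.000128) and bone disease factors 5 of 18 (0.0051). B cell and granulocyte genes each had 3 of 12 (0.0488), and without replicate 7 the number of lists enriched was 5. Fisher's exact test takes genes as independent, but members of most lists varied together, so these p-values can be too small. Its background, all genes tested, was not matched on expression. The other 12 lists, Wnt antagonists with 1 of 3 members among them, had an adjusted p of 0.0543 or higher. The immediate early score rose with the GAPDH 3′ to 5′ ratio (r = 0.481, rho = 0.476, adjusted p = 0.0263) and with the highest signal on the array (r = 0.443, rho = 0.424, adjusted p = 0.0435). Of these 12, the proteasome and proliferation lists had 0 members among the 294.

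Members of most lists varied together. In 15 of 19 lists the mean pairwise r between members exceeded that of random lists of matched size and expression (adjusted p from 0.00019, which rests on the smallest p of 0.0001 that 10000 random lists give, to 0.0308). Interferon response genes were the most coordinated (mean r = 0.347 over 26 members), with IFI27, IFIT1 (8.96 ± 1.77), LGALS3BP (10.13 ± 1.69) and IFIT3 (8.56 ± 1.42) spreading most. Of the lists that are not markers of another cell type, proliferation had 0.272, MHC class II 0.240 (HLA-DRA 12.06 ± 1.46, HLA-DPA1 11.77 ± 1.27, HLA-DPB1 9.86 ± 1.23, HLA-DQB1 8.65 ± 1.11), and the unfolded protein response and ER chaperones 0.198 (DDIT3 10.20 ± 1.43, SEL1L 11.73 ± 0.92, SSR1 13.52 ± 0.78, ERN1 7.97 ± 0.78). Proteasome genes had a mean r of 0.169 at bright and even levels (PSMA7 10.64 ± 0.78, PSMA3 12.37 ± 0.60, PSMD12 11.20 ± 0.56, PSMC1 12.37 ± 0.56). Immediate early genes had 0.161, NF-kappaB targets 0.148 (CCND2, TNFAIP2 9.87 ± 1.45, CD44 11.17 ± 1.39, BIRC2 10.16 ± 1.25) and plasma cell genes 0.107. The plasma cell list held the widest spreads in CD27, the joining chain gene JCHAIN (14.03 ± 1.75), the adhesion molecule gene NCAM1 (10.51 ± 1.46) and CAV1 (11.77 ± 1.24), while SDC1, which encodes the CD138 used for selection, stood at 15.23 ± 0.56 (all SD, n = 36). The plasma cell score moved with the highest signal on the array (r = 0.583, rho = 0.550, adjusted p = 0.0040) and with the GAPDH 3′ to 5′ ratio (r = 0.464, rho = 0.423, adjusted p = 0.0342). B cell, Wnt, adhesion and cyclin D lists had mean r from 0.0177 to 0.0489 and did not pass.

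**Figure D3:**
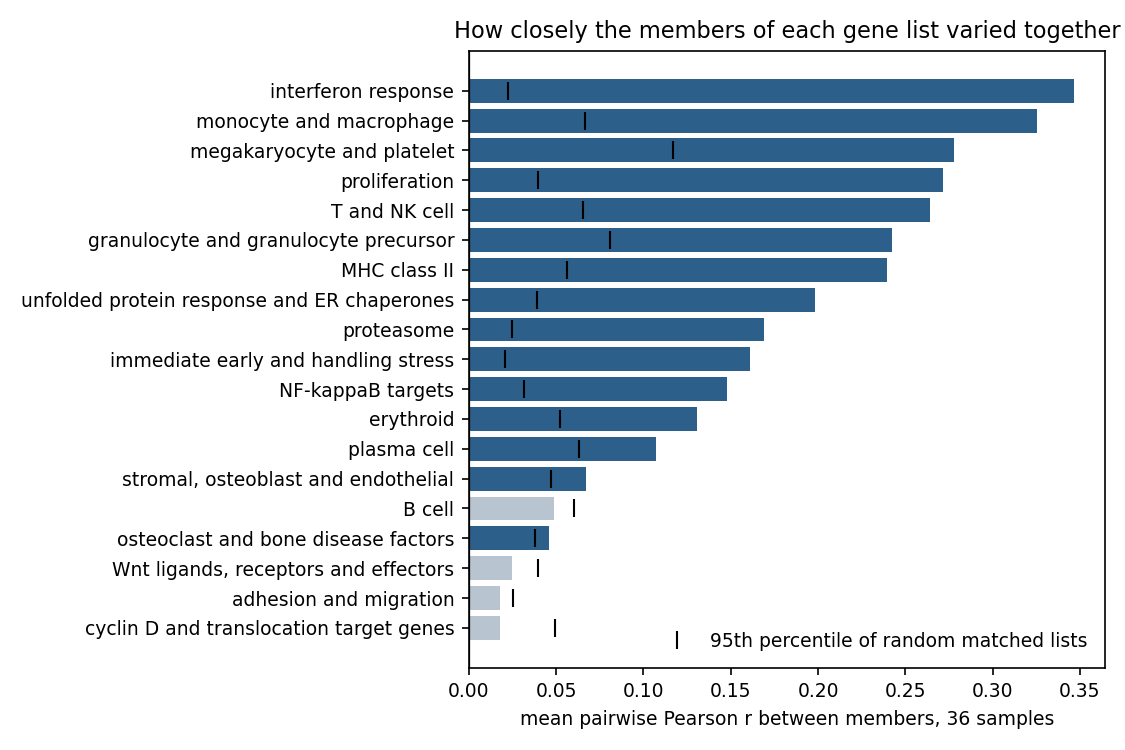
Mean pairwise Pearson r between the members of 19 gene lists over 36 samples (bars, dark where the adjusted p passes), with the 95th percentile of random matched lists as a tick. The interferon response reaches 0.347 where random lists reach 0.0226, and bone disease factors pass narrowly at 0.0458 against 0.0379.

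Of the 7 lists fixed as markers of cells other than plasma cells, 6 had members that varied together. Which cells expressed these genes was not measured, and CAV1, on the stromal list, also stood on the plasma cell list. Monocyte and macrophage genes had a mean r of 0.326, with LYZ (9.19 ± 1.96), S100A9 (8.03 ± 1.76), S100A8 (9.88 ± 1.73) and TYROBP (8.33 ± 1.70) varying most. The median of S100A9 lay near the floor, and its scaled median absolute deviation was 0.01. T and NK cell genes had 0.264 (CD28 7.92 ± 1.60, NKG7 9.34 ± 1.09, PRF1 9.18 ± 1.04, GNLY 7.31 ± 1.0011, of which CD28 and GNLY had medians at or near the floor and SDs of 0.97 and 0.53 with the floor at the 40th percentile), and granulocyte genes 0.242 (RNASE2 9.31 ± 1.73, PRG2 9.51 ± 1.64, CLC 8.77 ± 1.53, LTF 8.84 ± 1.23). Megakaryocyte and platelet genes had 0.278 over 6 members (PPBP 9.03 ± 1.64, PF4 9.56 ± 1.41, SELP 7.85 ± 0.91, ITGA2B 11.29 ± 0.59). Erythroid genes had 0.131 (HBB 12.02 ± 1.60, SLC4A1 8.48 ± 1.09, HBD 9.80 ± 1.07, SPTB 10.29 ± 0.83), and stromal, osteoblast and endothelial genes 0.0668 (CXCL12 10.22 ± 1.62, SPARC 9.13 ± 1.28, CAV1, IGFBP7 8.14 ± 1.22). B cell genes such as MS4A1 (8.52 ± 2.0035), FCER2 (8.74 ± 1.67), CD79A (11.55 ± 1.52) and BLK (8.01 ± 1.32) had a mean r of 0.0489 and did not pass. The median signal of the array rose with the stromal (r = 0.716, rho = 0.644), megakaryocyte (r = 0.688, rho = 0.601), erythroid (r = 0.574, rho = 0.598), T and NK cell (r = 0.533, rho = 0.505) and B cell scores (r = 0.531, rho = 0.545), each with an adjusted p of 0.0088 or lower. With that median as a covariate, an alternative chosen after seeing the data, the stromal list had a mean r of 0.00995 and bone disease factors 0.0122, and neither passed. With the filter of 18 samples the monocyte list (0.114), the erythroid list (0.0620), the stromal list (0.0673) and bone disease factors (0.0485) did not pass either. With quantile normalization the stromal list (0.0305) and bone disease factors (0.0319) did not pass, and bone disease factors also lost the call with the floor at the 40th percentile (0.0387), no filter (0.0295), ranks (0.0414) or the array background as covariate (0.0278). The erythroid list also lost its call with no filter (0.0844).

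Between list scores, 10 of 171 pairs passed, 9 positive and 1 negative. Monocyte and granulocyte scores rose together (r = 0.737, rho = 0.738, adjusted p = 0.00057, n = 36), at 0.740 without the 2 samples farthest from the median of the first score. B cell and proteasome scores ran in opposite directions (r = -0.683, rho = -0.706, adjusted p = 0.00057, and -0.660 without 2 samples). The unadjusted p of 1e-05 for both pairs, and for megakaryocyte with stromal scores, is the smallest 100000 permutations can give. Megakaryocyte with stromal (r = 0.730, rho = 0.655, without 2 samples 0.586), erythroid with stromal (r = 0.634, rho = 0.590, without 2 samples 0.634) and erythroid with megakaryocyte scores (r = 0.576, rho = 0.586, without 2 samples 0.531) rose together, with adjusted p = 0.00057, 0.0021 and 0.0075. Bone disease factors rose with cyclin D and translocation targets (r = 0.571, rho = 0.583, adjusted p = 0.0091, without 2 samples 0.537). The cyclin D list did not pass for coherence (mean r 0.0177), so its score does not stand for 1 shared change. IL6 and FGFR3, with gaps over 1 SD as single genes, are members of these 2 lists. The largest gaps of the 2 scores were 0.232 and 0.502 SD. T and NK cell scores rose with monocyte (r = 0.541, rho = 0.454), megakaryocyte (r = 0.502, rho = 0.454) and granulocyte scores (r = 0.494, rho = 0.456), and megakaryocyte with MHC class II scores (r = 0.485, rho = 0.483), with adjusted p from 0.0161 to 0.0475 and r without 2 samples of 0.445, 0.506, 0.434 and 0.417. Without those samples the T and NK cell pairs with monocyte and granulocyte scores and the MHC class II pair did not pass (adjusted p = 0.0859, 0.105 and 0.121). Over the other 7 pairs the unadjusted p ran from 5e-05 to 0.0028, and on ranks from 0.00017 to 0.0062. The 3 T and NK cell pairs and the MHC class II pair did not pass on ranks (adjusted p from 0.0686 to 0.0801). With the array median as a covariate, 3 pairs passed: B cell with proteasome (r = -0.548), monocyte with granulocyte (r = 0.708), and proliferation with proteasome (r = 0.610), which did not pass without it (r = 0.414, adjusted p = 0.1109). The erythroid, megakaryocyte and stromal pairs had r from 0.315 to 0.484 and did not pass, nor did bone disease factors with cyclin D targets (r = 0.480). Of 13 alternatives, T and NK cell with granulocyte scores did not pass under 7, erythroid with megakaryocyte and megakaryocyte with MHC class II scores under 6 each, T and NK cell with megakaryocyte scores under 5 and with monocyte scores under 4. Bone disease factors with cyclin D targets did not pass under 3, and megakaryocyte with stromal and erythroid with stromal scores under 2 each. The proteasome score fell with the array median (r = -0.561, rho = -0.563), the GAPDH 3′ to 5′ ratio (r = -0.563, rho = -0.585) and the BioB spike-in level (r = -0.563, rho = -0.559), with adjusted p of 0.0064 or lower. The B cell score rose with the array median (r = 0.531) and, on ranks, with the GAPDH ratio (rho = 0.453, adjusted p = 0.0368). The B cell list did not pass for coherence (mean r 0.0489), so its score does not stand for 1 shared change.

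**Figure D4:**
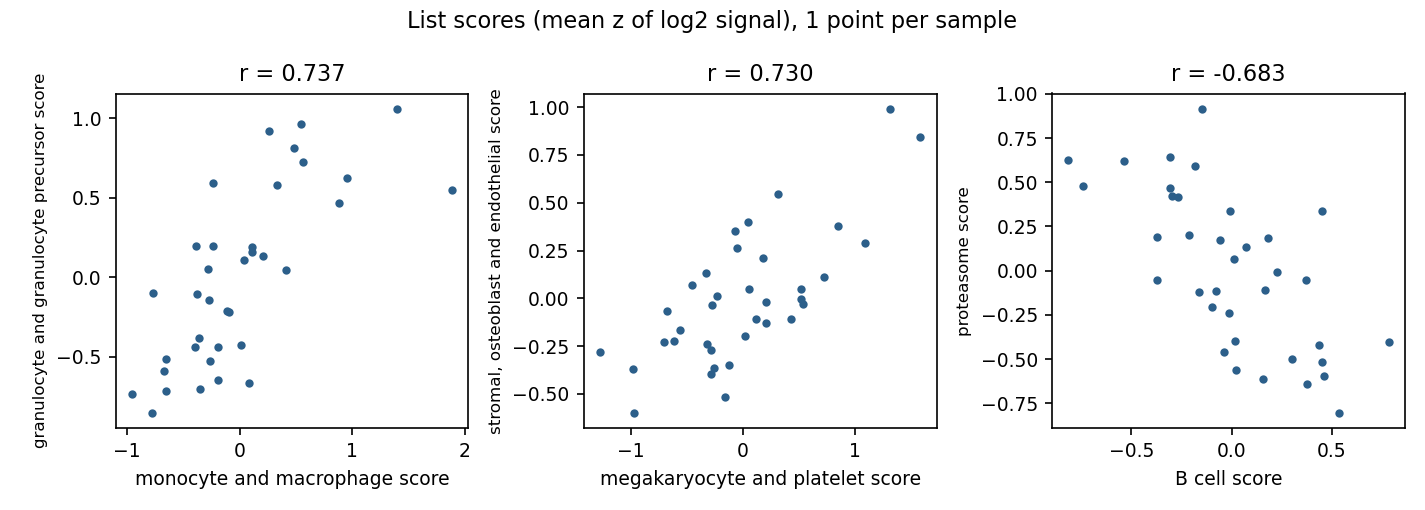
List scores, the mean of the members' standardised log2 signals, set against each other for 3 pairs of lists, with 1 point for each of 36 samples. Monocyte and granulocyte scores rise together (r = 0.737), as do megakaryocyte and stromal scores (r = 0.730), and B cell and proteasome scores run opposite (r = -0.683).

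Outside the list that defined it, 10 genes rose with the proliferation score, while 2 passed on ranks and 2 without the 2 samples farthest from its median. All 35 measured members had a positive r with the mean of the other members, from 0.0019 for MCM5 to 0.839 for ZWINT, and the members with the widest spread were UBE2C (8.46 ± 1.29), CKS2 (10.37 ± 1.20), RRM2 (8.44 ± 1.17) and CCNE2 (8.72 ± 1.13). Outside the list, limma called 10 of 5838 genes, all higher with the score, and 332 had an unadjusted p under 0.05. The adjustment ran over all 5873 genes, including the 35 members that define the score. Members have low p by construction, which lowers the adjusted p of other genes. The count and the limma adjusted p over all genes are therefore more lenient than an adjustment over the 5838 genes alone. The mitotic kinesin gene KIF2C rose by 0.67 ± 0.11 (SE, n = 36) log2 units per SD of the score (adjusted p = 0.000255 by limma), the Aurora kinase gene AURKB by 0.47 ± 0.08 (0.000242) and PCLAF, which encodes a partner of the replication clamp, by 0.50 ± 0.08 (0.000377). Other genes called were HMGB2 (slope 0.54), the histone methyltransferase gene EZH2 (0.50), the spindle genes SPAG5 (0.48), TPX2 (0.41) and KIF14 (0.35), STMN1 (0.34) and the histone gene H2AX (0.34), with adjusted p from 0.00151 to 0.0279. On the negative side 0 genes passed. The lowest p there belonged to CNOT2 (slope -0.28 ± 0.07, adjusted p = 0.103), MTMR3 (-0.24 ± 0.07, 0.170), PURA (-0.35 ± 0.10, 0.172), the chemokine receptor gene CXCR4 (-0.39 ± 0.11, 0.186) and SMTN (-0.36 ± 0.11, 0.197). Adjusted over the list alone, CXCR4 passed within adhesion and migration (0.0292), and XBP1, a transcription factor of secretory cells, within the plasma cell (0.0213) and unfolded protein response lists (0.0361), at a slope of -0.24 ± 0.07. In the other 16 lists 0 members passed either way. Without the 2 samples farthest from the median score, 2 genes passed, PCLAF and STMN1, and on ranks 2 passed, KIF2C and PCLAF. The slopes of the 8 genes whose calls were lost without those samples stayed positive, at 0.59 for KIF2C, 0.53 for EZH2, 0.49 for HMGB2, 0.45 for SPAG5, 0.44 for AURKB, 0.36 for H2AX, 0.34 for TPX2 and 0.21 for KIF14. Some calls also ended without a single sample, with slopes from 0.27 for KIF14 to 0.52 for EZH2: HMGB2 did not pass without replicate 26 (adjusted p = 0.0535), EZH2 without replicate 3 (0.0507) or 26 (0.0535), KIF14 without replicate 9 (0.0585) or 26 (0.298), and H2AX without replicate 3, 9, 15, 24 or 26 (0.05 to 0.124). With the GAPDH 3′ to 5′ ratio as a covariate EZH2 (slope 0.43, adjusted p = 0.137), KIF14 (0.34, 0.0545) and H2AX (0.37, 0.0548) did not pass, nor did H2AX with the blood and marrow cell scores (0.34, 0.146). On the negative side MTMR3 passed without replicate 6 (0.0485) and SMTN without replicate 9 (0.0356).

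DKK1 itself did not follow any measure of array quality. Its r was -0.0528 with the GAPDH 3′ to 5′ ratio, 0.266 with that of beta-actin, -0.114 with the BioB spike-in level, 0.0195 with the array median and -0.0161 with the highest signal, with adjusted p from 0.319 to 0.955 and rho from -0.119 to 0.0918. Over all list scores and DKK1, 15 of 100 relations with these measures passed, and each has been given beside its list. Their unadjusted permutation p ran from 1e-05 to 0.0065 and on ranks from 6e-05 to 0.0104, and r without the 2 samples farthest on the array measure had the same sign in all 15, with sizes between 0.376 for immediate early genes and 0.647 for stromal genes. Of the 100 relations, 5 passed without those 2 samples and 7 with quantile normalization. On ranks 17 relations passed. Plasma cell with the GAPDH ratio and immediate early genes with the highest signal did not (adjusted p = 0.0548 for both). Passing on ranks only were B cell with the GAPDH ratio (rho = 0.453, adjusted p = 0.0368) and proteasome with the highest signal (-0.483, 0.0271). So were immediate early genes with the beta-actin ratio (0.478, 0.0273) and cyclin D targets with the array median (0.445, 0.0426).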

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

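The covariates array background, array maximum and array median were chosen after seeing the data. No paired analysis was possible because the samples form 1 group with nothing to pair. The arrays arrived scaled, so no further scaling moved nothing and says nothing about stability. Genes following DKK1 stayed at 0 under all 16 alternatives and with each sample left out (0 to 0), and single gene relations stayed at 0 under the 12 alternatives run for them (0 to 0 with each sample left out). List scores following DKK1 numbered 1 with blood and marrow cell scores as covariates, and 0 to 1 with each sample left out (1 without replicate 23, 0 otherwise); camera called 1 list with an estimated correlation in place of 2. The r of DKK1 with DKK4 reversed to 0.0832 without the 2 farthest samples and ranged from -0.209 to 0.0253 with each sample left out, and the slope of GNB2 reversed to 0.0167 with the probe set of highest SD. The mean of DKK1 stayed between 8.32 and 8.46 with each sample left out. Its SD moved to 1.67 with the floor at the 5th percentile, 0.918 at the 40th and 1.09 without the 2 farthest samples, and ranged from 1.19 to 1.33 with each left out, so low signal limits it. Pairs of lists past the threshold went from 10 to 6 with quantile normalization, 20 with no filter and 3 with the array median as covariate; the cause was not tested. B cell with proteasome and monocyte with granulocyte passed under all 13 alternatives. Coherent lists numbered 11 to 15 over 12 alternatives; 11 was with the filter of 18 samples, which tests fewer genes. Relations with array measures went from 15 to 7 with quantile normalization and 5 without the 2 farthest samples, and numbered 17 on ranks. Genes with an SD over 1 went from 859 to 418 with the floor at the 40th percentile and 474 with the filter of 18 samples, and 178 had an SD over 1.5; with each sample left out they numbered 846 to 872, and enriched lists 5 to 10 (5 without replicate 7). Genes following the proliferation score went from 10 to 2 on ranks and 2 without the 2 farthest samples, and 7 to 11 with each sample left out (7 to 11 higher, 0 to 1 lower, the 1 without replicate 6 or 9). The 1 lower gene was CNOT2 with the floor at the 40th percentile, no filter or array weights, and FUT8 with the array maximum as covariate. Over 180 comparisons of the 15 coherent lists, 167 kept their call and 13 lost it; over 755 comparisons of the SD of 87 named genes, 621 moved by less than its sampling error. Samples over the mark numbered 2 for CCND2 with quantile normalization, 3 for CCND2 and 1 for CDKN2A at 1.5 above the median, and 1 for ITGB7 at 3 above.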

Other observations

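Immunoglobulin genes, counted apart because each clone fixes its own, were among the most uneven transcripts of these samples. Of 13 tested, 11 had an SD over 1: the heavy chain probe set IGH stood at 12.66 ± 2.41 (SD, n = 36), the lambda constant gene IGLC1 at 13.79 ± 2.32, IGHD at 9.81 ± 1.92 and the kappa constant gene IGKC at 12.04 ± 1.79. The surrogate light chain gene IGLL1, normally a gene of B cell precursors, lay at the floor in 22 samples and above the median of its array in 9 (7.83 ± 1.68). The probe set for IGHG1 (9.90 ± 0.55) was even at a low signal, at most 1967 where IGLC1 reached 73369. Its evenness may not describe IGHG1 transcripts. These genes were named after their values were seen.

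Some genes of the plasma cell list were bright and even. SSR4, of the ER translocon (15.67 ± 0.49), XBP1 (15.12 ± 0.47) and the coactivator gene POU2AF1 (14.49 ± 0.37, all SD, n = 36) had SDs below the median of 0.61 over all genes, as did the proteasome list, with a median SD of 0.43 over 26 members, but the 13 members of the plasma cell list had a median SD of 0.63 and JCHAIN varied by 1.75. Bright members of the immediate early and handling stress list differed in spread, from FOS (13.67 ± 1.54) to JUND (15.50 ± 0.51) and ZFP36 (14.95 ± 0.50). The genes of this paragraph were named after their values were seen.

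The test of the SD of DKK1 was chosen after the result was seen, as were the array median and background as covariates. The other tests below were written down before their results, but the test of admixed marrow cells was given a further condition afterwards. No biological explanation was tested for the patterns below, since the labels give no group that would separate the samples.

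Erythroid, megakaryocyte and stromal scores rose and fell together although CD138 selection should remove such cells. An offset shared equally by all dim probe sets would give random lists of matched expression a similar r. The lowest of the 3 pairwise r, 0.576, lay at percentile 99.64 among 10000 random pairs, which argues against such an offset as the whole cause. The random lists were matched on expression only, so an offset acting more on these lists than on other genes was not tested. HBB, PPBP and PF4, at mean log2 signals of 12.02, 9.03 and 9.56, followed the rest of their own lists at a mean r of 0.395. That r was above the bound written down beforehand for admixed marrow cells. A further condition, that the 3 pairs pass with the array median as a covariate, was added after seeing the data and was not met. What r a difference between arrays alone would give these genes was not tested. Admixed cells therefore cannot be told apart from a difference between arrays. The array median as a covariate lowered the 3 r from 0.576, 0.634 and 0.730 to 0.315, 0.396 and 0.484, and none then passed (adjusted p = 0.379, 0.209 and 0.094), so part of the pattern goes with the array median. All arrays had a common trimmed mean, so this median is not overall brightness. It may itself change with the mix of cells, so the covariate cannot separate the 2 explanations. Of the members measured, 8 of 12 erythroid, 4 of 6 megakaryocyte and 10 of 17 stromal genes had a mean above the typical array median, and 2 stromal genes stood on another list.

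Monocyte and granulocyte scores moved together more firmly. Their r of 0.737 lay at percentile 99.97 among random matched pairs and was 0.708 with the array median as a covariate. Both values argue against an offset shared equally by all dim probe sets. In the order of the samples, both scores were positive in each of replicates 13 to 18 and negative in each of 19 to 21. Both scores were mostly negative in replicates 1 to 12, and their signs varied in 22 to 36. The log2 GAPDH 3′ to 5′ ratio was positive in each of replicates 1 to 11 and of both signs later. The labels give no batch, so a difference between runs of arrays was not tested. The permutation tests treat the arrays as exchangeable and do not allow for such runs. Admixed myeloid cells, which CD138 selection should remove, stay open as a candidate source: the 4 brightest members of each list followed the other list at a mean r of 0.310, between the bounds set beforehand, with S100A8 at 0.587 and RNASE2 at 0.552 but AIF1 at 0.0931 and CST3 at 0.127. CST3, CD68 and PRG2 had mean log2 signals of 11.05, 10.05 and 9.51, levels that do not measure the share of such cells, and 5 of 14 monocyte and 4 of 12 granulocyte genes lay above the typical array median.

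No gene passed the test against DKK1. The 311 genes at an unadjusted p under 0.05 were matched or exceeded in 26 of 100 permutations of DKK1, with up to 601 genes, so chance cannot be excluded for that number, which does not say why no gene passed. Whether the differences in DKK1 are measurement noise cannot be told apart from real differences here: its SD lay at percentile 91.56 among 557 genes of similar level, above their median of 0.85 and below their 95th percentile.

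The 10 genes following the proliferation score were matched in 0 of 100 permutations of that score, which gave at most 1 gene. The list members followed the score by construction only in the observed fit, which eased the adjusted threshold there. The observed and permuted counts are therefore not fully comparable. The r of -0.683 between B cell and proteasome scores lay at percentile 0.01 among random matched pairs of lists.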
